A study of Mus musculus with 9 samples.

How the data were processed

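RNA sequencing measured gene expression in 9 samples of organoids, small epithelial fragments freshly isolated from mammary tumours of MMTV-PyMT mice, in which a viral oncogene drives breast cancer. Per the labels, all mice were FVB/NJ and all organoids were exposed overnight to an adenovirus that delivers Cre recombinase, then grown for 48 h in collagen I gels with FGF2. The 4 WT samples carried normal alleles of Cdh1, the gene for E-cadherin, and the 5 E-cad-KO samples carried floxed alleles that Cre can delete. The series' design text calls the samples biological replicates. The labels do not name the animals, so p-values measure the spread between these samples.

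The deposited table holds raw counts per gene for each sample, not normalised. Per the labels' protocols, gels were frozen whole, RNA was purified on RNeasy columns and libraries were made with a stranded TruSeq kit that selects mRNA. Per the submitters' processing notes, Bowtie2, TopHat2 and HTSeq were used with the GRCm38 genome build. Their versions and settings, the annotation release and whether counting used the strand are not given in the sources used here. Because whole gels were extracted, RNA of any other cell carried along with the epithelium is part of the counts. Because the strand setting is not known here, a gene whose exons overlap a gene on the other strand could share reads with it, and such genes are marked in the text. The counts of a gene cover all its exons, so transcripts that keep exons outside a floxed part are counted.

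The table has 51912 genes, of which 51633 had a symbol in the name table. The 279 without one held 0.045% to 0.053% of the counts of a library. Every row named a gene, and every value column belonged to a sample. Positions, transcript lengths, GC content and exon overlaps came from GENCODE release M21 on GRCm38. Unless CCDS is named, length and GC content are those of a gene's longest annotated transcript, which need not be the one expressed. Library totals ran from 44890302 to 64763645 counts. Expression is given as counts scaled to a common library size (CPM), of which 1 was 44.9 counts in the smallest library. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 14.9.

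The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors, robust dispersion estimates, the default filterByExpr filter (17289 genes tested), group as the only term and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. All p-values are two-sided. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes and are given as mean ± SD. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 36 lists with at least 5 tested members. A list's score in a library is the mean of its members' log2 CPM after centring each gene on its mean over the 9 libraries. Principal components used the 500 most variable genes.

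Before the data were examined, the design, the 38 gene lists, most alternatives and the rule for naming genes were fixed. The rule names Cdh1, the 12 largest rises and 12 largest falls among called genes with at least 5 CPM in the higher group (leaving out predicted genes), up to 4 members of each described list by smallest p together with called members that go against the list, and 19 genes of epithelial or mesenchymal character, of which 1 is not reported here. The alternatives were size factors by median of ratios or upper quartile, filters of at least 1 count or of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, each library left out, a minimum fold of 1.5, non-robust dispersions, estimated list correlations, fry, and lists without genes of other cell types. Chosen after seeing the data were a macrophage score as covariate, WT libraries 1 and 4 left out, and offsets for transcript length and GC content.

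The routines were tested on simulated counts for this comparison, drawn for the 17289 tested genes with the real means and library sizes and with 200 genes changed. With dispersions estimated per gene, edgeR recovered 41.8% of genes changed 1.5-fold, 70.1% of those changed 2-fold and 90.9% of those changed 4-fold, and 8.2% of its calls were false. A limit of 20% false calls had been set beforehand. Among the alternatives, limma-voom stayed under it with 7.9%, and DESeq2 went over it with 20.5%. Calling DESeq2 without the wrapping function gave the identical calls, so the excess did not come from that function. A second simulation, added after this outcome, used dispersions on the fitted trend and gave 5.5% false calls for edgeR, 4.3% for limma-voom and 20.9% for DESeq2. DESeq2 was kept as an alternative because it had been fixed as one. With no gene changed, edgeR called 0 genes, and a planted list of 20 genes raised by 0.4 on the log2 scale was called by camera (adjusted p = 4.34e-16) along with 1 list that held no planted change. Each gene was simulated independently, so variation shared between genes was absent. These figures therefore need not hold for the real libraries.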

Results

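Gene expression was measured by RNA sequencing in organoids from MMTV-PyMT mouse mammary tumours after exposure to adeno-Cre, in 4 samples with normal Cdh1 (WT) and 5 samples with floxed Cdh1 (E-cad-KO). Library totals were 62686366, 64763645, 60736621 and 52603695 counts in WT 1 to 4. They were 54894722, 60157007, 44890302, 48307033 and 62416955 counts in E-cad-KO 1 to 5. The comparison asked how the transcriptome of tumour organoids in collagen I differs once E-cadherin, the cell adhesion molecule of epithelial adherens junctions, is targeted by Cre. In E-cad-KO organoids Cdh1 fell to about 0.482 of the WT level, and targets of YAP and TAZ were higher as a list (adjusted p = 0.0098 with an estimated correlation). By camera with a preset correlation, actomyosin and interferon response genes were also higher (adjusted p = 0.173 and 0.472 with an estimated correlation). Milk genes were lower, with 3 of 14 members called (adjusted p = 0.173 with an estimated correlation). EMT transcription factors and mesenchymal effectors were not called as lists.

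Cdh1 (ENSMUSG00000000303; GRCm38 chromosome 8, 106603351 to 106670246) was lower in every E-cad-KO library than in every WT library. It stood at 189 ± 44.1 CPM in WT (SD, n = 4) and 91.3 ± 15.5 CPM in E-cad-KO (SD, n = 5). The WT libraries held 246.5, 150.3, 201.2 and 159.3 CPM, and the E-cad-KO libraries held 86.5, 118.3, 85.2, 87.3 and 79.0 CPM. The Cdh1 log2 fold change was -1.05 (SE 0.16, edgeR adjusted p = 0.0275). The labels do not say which exons are floxed, the counts cover the whole gene, and they cannot separate transcripts of deleted alleles from those of cells in which Cre did not act. The call was lost without WT 3 (edgeR adjusted p = 0.0904), E-cad-KO 1 (0.0664), E-cad-KO 3 (0.0764), E-cad-KO 4 (0.0657) or E-cad-KO 5 (0.0644), and without both WT 1 and WT 4 (0.0545, log2 fold change -0.94). Over the 19 alternatives that recorded it, the adjusted p of the Cdh1 log2 fold change ran from 5.5e-08 to 0.171, always with a negative value. Tested against a minimum fold of 1.5, no gene was called, Cdh1 included.

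**Figure D1:**
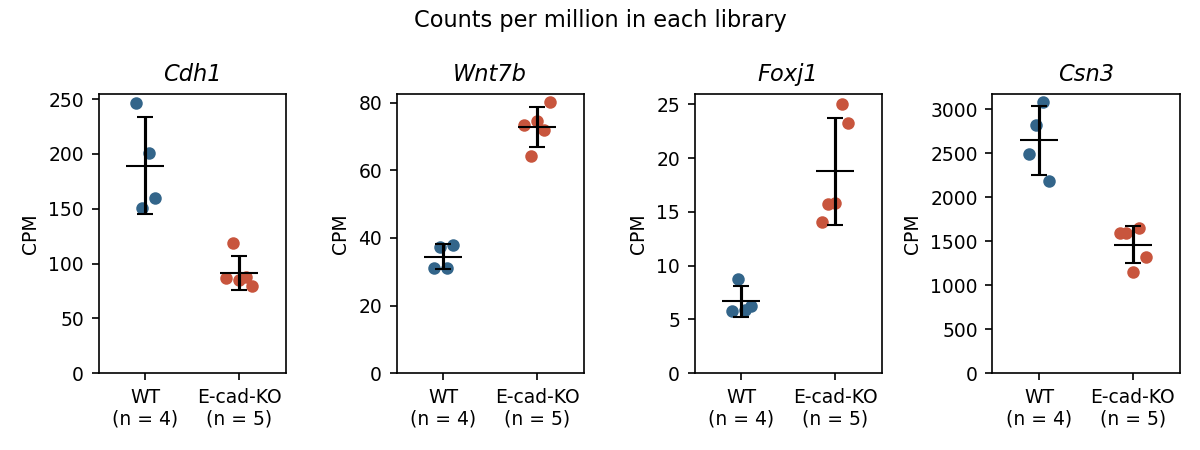
Expression in CPM (vertical axes, starting at 0) of Cdh1, Wnt7b, Foxj1 and Csn3 in each WT (blue) and E-cad-KO (red) library, with black lines for the group mean ± SD. For each of the 4 genes, the WT and E-cad-KO libraries occupy separate ranges, for example 31.2 to 38.0 CPM in WT and 64.1 to 80.2 CPM in E-cad-KO for Wnt7b.

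Across the transcriptome, 244 of 17289 tested genes were called, 157 higher and 87 lower in E-cad-KO. Some of them, among them Mri1, Bst2, Mtus1, Bcar1 and Plcg2, lie on chromosome 8 as Cdh1 does. Whether sharing a chromosome with the floxed alleles bears on their values was not tested. The design cannot separate this from loss of E-cadherin. Most changes were modest: the median fold was 1.4 among genes called higher and 0.757 among genes called lower, and 19 genes changed at least 2-fold, 12 up and 7 down. The 2 groups did not overlap for 1402 genes, 8.11% of those tested against 1.59% expected by chance, and for 243 of the 244 called genes. With upper-quartile scaling the split turned to 123 higher and 151 lower. Single libraries moved the number of calls: it was 122 without WT 1, 105 without WT 2, 9 without WT 3 and 334 (193 higher, 141 lower) without WT 4. It was 29, 54, 28, 26 and 47 without E-cad-KO 1 to 5. Of the 244 genes, 95, 81, 9 and 187 were still called without WT 1 to 4, and 27, 53, 28, 26 and 44 without E-cad-KO 1 to 5. Against a minimum fold of 1.5, edgeR's glmTreat called 0 genes, with 234 at an unadjusted p under 0.05.

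Called genes with at least 5 CPM in the higher group were ranked, with predicted genes and RIKEN clones left out. Oas2, an interferon-induced antiviral enzyme, rose most (log2 fold change 1.61, SE 0.33), followed by Foxj1, the master regulator of motile cilia (1.49, SE 0.21). With 1 library left out at a time, Oas2 was called in 1 of 9 fits and Foxj1 in 8 of 9. Foxj1 went from 6.67 ± 1.43 CPM in WT (SD, n = 4) to 18.8 ± 4.98 CPM in E-cad-KO (SD, n = 5). Wnt7b, a secreted Wnt ligand, had the smallest adjusted p of the named genes (edgeR adjusted p = 0.00226) and rose from 34.4 ± 3.70 to 72.9 ± 5.82 CPM (SD, n = 4 and n = 5). Its exons overlap AU022754 on the other strand. Pde1c, a cyclic nucleotide phosphodiesterase, rose by a log2 fold change of 1.16, the methionine salvage enzyme gene Mri1 by 1.02 and the calcium channel gene Trpv4 by 0.98. Timp3, an inhibitor of matrix metalloproteinases whose exons overlap Syn3 on the other strand, went from 290 ± 87.7 to 577 ± 72.0 CPM (SD, n = 4 and n = 5). Heg1 (0.96, overlapping Gm15657), Bst2 (0.94), Irf7 (0.92, overlapping Phrf1), the interleukin-18 receptor subunit gene Il18rap (0.91) and Thsd4 (0.91) completed the 12 largest rises.

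Under the same limits the largest fall was in Pde9a, another cyclic nucleotide phosphodiesterase, with a log2 fold change of -1.29 (SE 0.22). Its exons overlap 2 unnamed genes on the other strand. It was followed by the whey protein gene Wap (-1.14, SE 0.20), the glutamate decarboxylase gene Gad1 (-1.11, SE 0.22), the alpha-lactalbumin gene Lalba (-1.08, SE 0.18) and Cdh1 itself. Folr1, a folate receptor, fell from 57.7 ± 14.7 to 29.0 ± 4.07 CPM (SD, n = 4 and n = 5), and Csn3, kappa-casein, from 2646 ± 390 to 1462 ± 215 CPM (SD, n = 4 and n = 5). Mtus1 (-0.84), Arhgdib (-0.78), Tspan15 (-0.78), Fam181b (-0.70) and the dipeptidyl peptidase gene Dpp4 (-0.70) made up the rest. Of these 5, all but Tspan15 overlap exons of a gene on the other strand. So do Tnc, Fn1, Zeb1, Zeb2, Ctnnb1, Ctnna1, Actn1, Krt8, Oasl1 and Tgfb2 among the genes named further on, and Ctnnd1 overlaps a gene on its own strand.

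**Figure D2:**
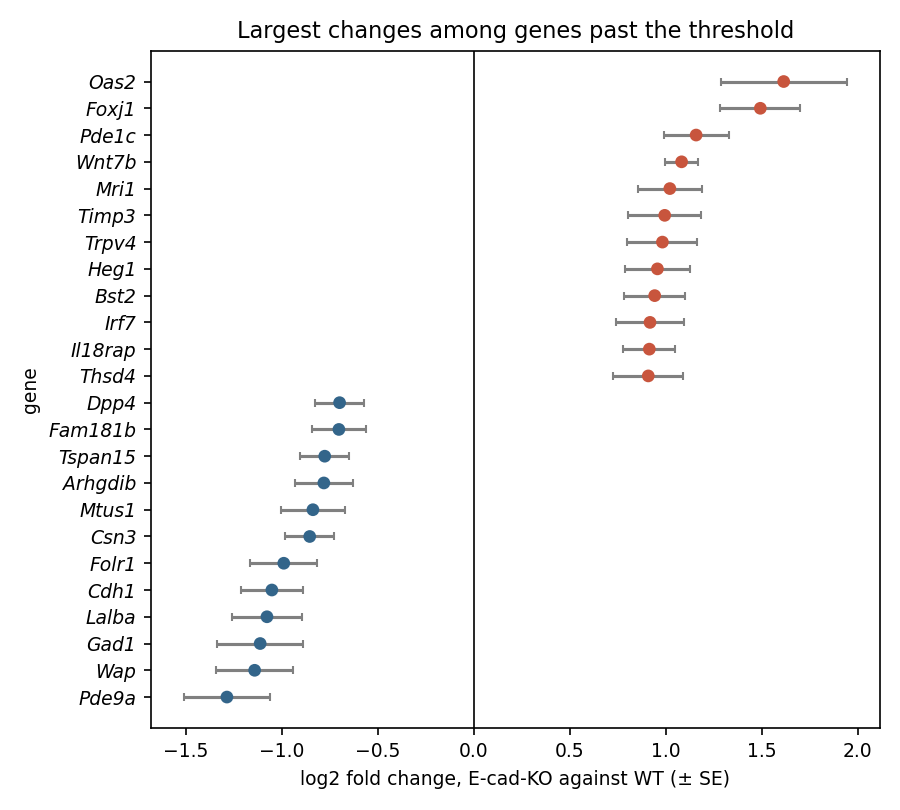
Log2 fold change of E-cad-KO against WT (horizontal axis) with its standard error for the 24 genes with the largest rises (red) and falls (blue). They were ranked among called genes with at least 5 CPM in the higher group, predicted genes and RIKEN clones left out. Values run from -1.29 for Pde9a to 1.61 for Oas2.

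Of 36 gene lists tested, 15 were called by camera, 13 higher and 2 lower in E-cad-KO. Some lists share genes, so their results are not independent. Members also found in another list were 9 of 26 for TGF-beta response and 8 of 16 for TGF-beta ligands and receptors. They were 6 of 13 for integrins and 6 of 22 for p53 targets. With correlations estimated for each list, only the YAP and TAZ targets remained past the threshold. Their own camera p rose from 7.36e-10 to 0.000272 although their estimated correlation was -0.033, below the preset 0.01. A larger p with this setting therefore does not by itself show that members vary together. The directional test of fry called 5 lists: YAP and TAZ targets, TGF-beta response, actomyosin, milk, and immediate early and heat shock genes. Targets of YAP and TAZ, mechanically regulated transcriptional coactivators, rose together. Of 20, 18 had a positive log2 fold change, 5 were called over all genes tested and 13 when adjusted over the list alone, all higher (median log2 fold change 0.36, camera adjusted p = 2.65e-08; adjusted p = 0.0098 with an estimated correlation). Asap1 (0.50, SE 0.07), Arhgef17 (0.33, SE 0.06), the ectonucleotidase gene Nt5e (0.47, SE 0.09) and Nuak2 (0.66, SE 0.14) were among the called members. The list's score was -0.21 ± 0.07 in WT (SD, n = 4) and 0.16 ± 0.02 in E-cad-KO (SD, n = 5), with no overlap between libraries.

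Actomyosin genes, which build the contractile cytoskeleton, were higher for 20 of 22 members, 1 called over all genes tested and 12 adjusted over the list alone (median 0.24, camera adjusted p = 1.67e-07; adjusted p = 0.173 with an estimated correlation). Tropomyosin Tpm1 rose by 0.37 (SE 0.07), while the non-muscle myosin gene Myh9 stood at 0.35 (edgeR adjusted p = 0.0574) and the actinin gene Actn1 at 0.44 (edgeR adjusted p = 0.0853). Of the TGF-beta response genes, 23 of 26 had a positive log2 fold change. By edgeR 0 were called over all genes tested, and 10 higher and 1 lower adjusted over the list alone (median 0.24, camera adjusted p = 5.14e-06; adjusted p = 0.173 with an estimated correlation). The feedback genes Pmepa1 (0.43), Tgif1 (0.28) and Smad7 (0.39) and the oxidase gene Nox4 (0.80) had its smallest p-values. Among TGF-beta ligands and receptors, 12 of 16 were higher, with 1 call over all genes tested and 2 adjusted over the list alone (camera adjusted p = 0.00342; adjusted p = 0.428 with an estimated correlation). The called member was the latent TGF-beta binding protein gene Ltbp1 (0.46, SE 0.06). Smad3 stood at 0.26, Tgfbr2 at 0.22, Tgfb1 at 0.23 and Tgfb2 at -0.22, none of them called. Integrins were higher for 11 of 13 members, 1 called over all genes tested and 1 adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.352 with an estimated correlation). The called member was the laminin receptor subunit gene Itga3 (0.53, SE 0.11). The integrin call was lost without WT 4 (camera adjusted p = 0.0821) or E-cad-KO 3 (0.0589), without both WT 1 and WT 4 (0.0915) and with length and GC offsets (0.0747).

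**Figure D3:**
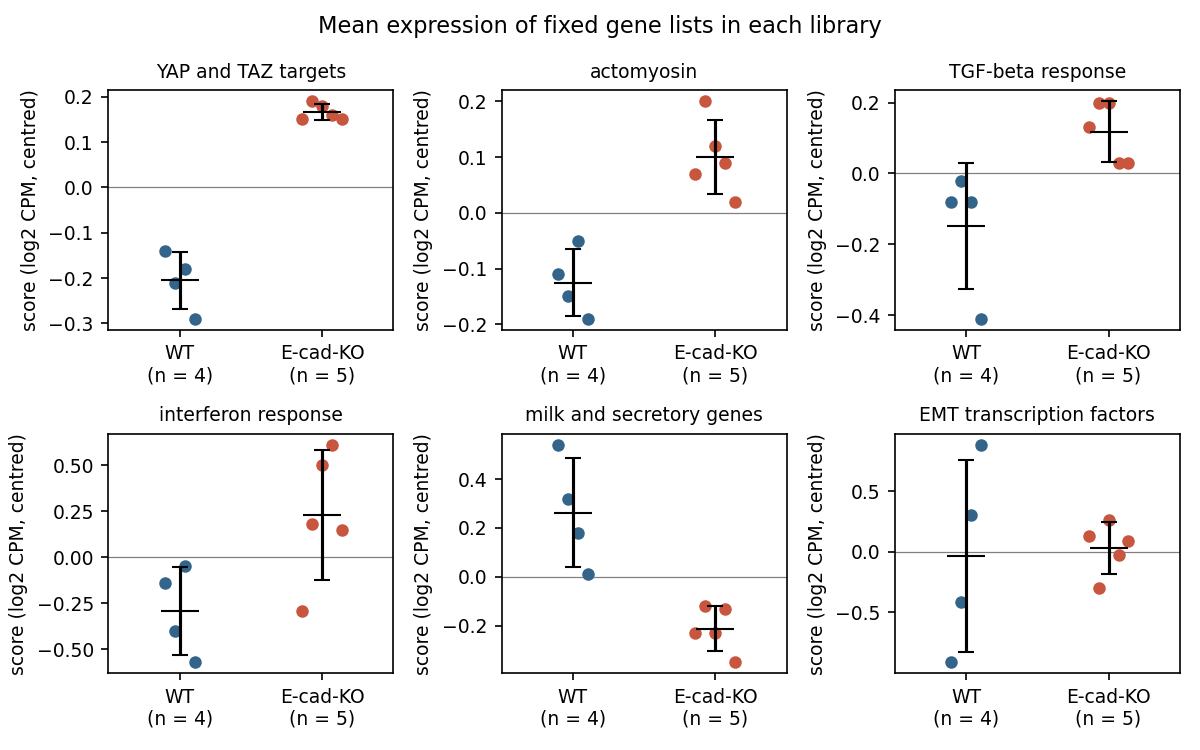
Score of 6 gene lists (vertical axes, mean centred log2 CPM of the members) in each WT (blue) and E-cad-KO (red) library, with black lines for the group mean ± SD. The groups do not overlap for YAP and TAZ targets, actomyosin, TGF-beta response and milk genes, and overlap for the interferon response (WT -0.57 to -0.05, E-cad-KO -0.29 to 0.61) and the EMT transcription factors (WT -0.91 to 0.88, E-cad-KO -0.30 to 0.26).

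Interferon response genes had the largest median log2 fold change of the lists called, 0.59, with 19 of 21 higher, 2 called over all genes tested and 10 adjusted over the list alone (camera adjusted p = 2.6e-07; adjusted p = 0.472 with an estimated correlation). The called members were Bst2, a membrane protein that tethers viruses, and Irf7, a transcription factor of the interferon system. With 1 library left out at a time, Bst2 was called in 2 of 9 fits and Irf7 in 1 of 9. For Irf7 the groups overlapped, with 18.6 CPM in WT 3 and 18.2 CPM in E-cad-KO 1. Oasl1 (0.87) and Oas1a (0.84) were not called by edgeR. DESeq2, over its limit of false calls in simulations, called 10 members higher, these 2 among them, and limma-voom called 1. WT 4, which had the highest macrophage score of all libraries (2.48), had the lowest interferon score (-0.57). Inflammatory cytokine and NF-kB genes were higher for 13 of 20 members, with 2 called higher and 1 lower over all genes tested and 6 higher and 1 lower adjusted over the list alone (median 0.40, camera adjusted p = 0.00366; adjusted p = 0.472 with an estimated correlation). Ptgs2, the inducible prostaglandin synthase gene, rose from 160 ± 28.5 to 263 ± 21.3 CPM (SD, n = 4 and n = 5) and Nfkb2 rose by 0.47, overlapping Psd on the other strand. Lcn2, an iron-trapping protein, went against the list and fell from 4282 ± 202 to 3438 ± 167 CPM (SD, n = 4 and n = 5). Immediate early and heat shock genes were higher for 13 of 15 members, 1 called over all genes tested (Hsph1, 0.71) and 4 adjusted over the list alone (camera adjusted p = 0.00072; adjusted p = 0.279 with an estimated correlation). This list and the mitochondrially encoded mRNAs were classed as technical, not as pathways. Whether technical differences between samples bear on the immediate early and heat shock genes was not tested.

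Milk and secretory genes fell as a group. Of 14 tested, 11 had a negative log2 fold change and 3 were called, both over all genes tested and adjusted over the list alone: Csn3, Wap and Lalba (median -0.41, camera adjusted p = 0.00266; adjusted p = 0.173 with an estimated correlation). The score was 0.26 ± 0.22 in WT (SD, n = 4) and -0.21 ± 0.09 in E-cad-KO (SD, n = 5). Mitochondrially encoded mRNAs were lower for 12 of 13 members, with 0 called by edgeR over all genes tested, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05 (median -0.11, camera adjusted p = 0.0271; adjusted p = 0.472 with an estimated correlation). With offsets for transcript length and GC content their median was 0.02 (camera adjusted p = 0.922). The call was also lost without WT 4 (camera adjusted p = 0.146), E-cad-KO 2 (0.084) or E-cad-KO 5 (0.054), and without both WT 1 and WT 4 (0.254).

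The other junction and epithelial genes were not lower as lists. Tight junction genes were higher for 16 of 19 members, with 0 called over all genes tested and 2 adjusted over the list alone (camera adjusted p = 0.000683; adjusted p = 0.472 with an estimated correlation). The claudin genes Cldn7 and Cldn4 stood at log2 fold changes of 0.44 and 0.80. Adherens junction partners were higher for 13 of 14, with 0 called over all genes tested and 0 adjusted over the list alone (camera adjusted p = 0.0492; adjusted p = 0.773 with an estimated correlation). The catenin genes Ctnnb1 (0.00, SE 0.13), Ctnna1 (0.23, SE 0.10) and Ctnnd1 (0.13, SE 0.11) were not called. Epithelial identity genes were higher for 16 of 22, with 0 called over all genes tested and 1 adjusted over the list alone (camera adjusted p = 0.0202; adjusted p = 0.773 with an estimated correlation). Krt8, a luminal keratin, stood at 0.39 (edgeR adjusted p = 0.053), Krt14, a basal keratin, at -0.36 and Epcam at 0.17. The call of adherens junction partners was lost without WT 3 (camera adjusted p = 0.0957), WT 4 (0.412), E-cad-KO 2 (0.173) or E-cad-KO 3 (0.154). It was also lost without both WT 1 and WT 4 (0.0601), with length and GC offsets (0.277), with median-of-ratios size factors (0.0506) and with the 1 CPM filter (0.071). The call of epithelial identity was lost without WT 4 (camera adjusted p = 0.411), E-cad-KO 2 (0.122) or E-cad-KO 3 (0.0508), and without both WT 1 and WT 4 (0.124). Desmosomes and other cadherins were not called (camera adjusted p = 0.399 and 0.639), with Cdh2 at -0.05 and Cdh3 at 0.22. Desmosomes were called without WT 1 (camera adjusted p = 0.0145).

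EMT transcription factors, which drive the change from epithelial to mesenchymal character, were not called as a list (camera adjusted p = 0.797). By edgeR 0 of 10 were called over all genes tested, and adjusted over the list alone 2 were higher and 1 was lower. Snai1 stood at 0.68 (SE 0.21) and Twist1 at 0.56 (SE 0.18), against -0.74 (SE 0.63) for Zeb1, -0.50 (SE 0.55) for Zeb2 and -0.12 (SE 0.25) for Snai2. Over the alternatives Snai1 and Twist1 stayed positive. Zeb1 ran from -1.08 to 0.22, Zeb2 from -0.82 to 0.24 and Snai2 from -0.31 to 0.08. WT 4 held the most Zeb1 (25.8 CPM) and Zeb2 (26.5 CPM) of all libraries. Mesenchymal effectors were not called either (camera adjusted p = 0.149), though they were without WT 3 (0.0193) or WT 4 (0.00574). Of them 1 of 16 was called over all genes tested, the matrix protein gene Tnc (0.44, SE 0.08), and 2 adjusted over the list alone, both higher. Vim was at 314 ± 222 CPM in WT (SD, n = 4) and 264 ± 44.8 CPM in E-cad-KO (SD, n = 5), and Fn1 had a log2 fold change of 0.67 (SE 0.26). For EMT transcription factors, mesenchymal effectors and other cadherins, the median and mean were negative while camera's direction was upward. Scores of EMT transcription factors spread more within WT (SD 0.79) than within E-cad-KO (SD 0.21).

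Among genes of growth and death, p53 targets were higher for 19 of 22, with 0 called by edgeR over all genes tested and 0 adjusted over the list alone (camera adjusted p = 0.00266; adjusted p = 0.472 with an estimated correlation). ERK feedback genes and EGFR ligands were higher for 14 of 17, with 0 called over all genes tested and 3 adjusted over the list alone (camera adjusted p = 0.00562; adjusted p = 0.428 with an estimated correlation). The ligand genes Hbegf and Areg stood at 0.46 and 0.60. Pro-apoptotic genes (camera adjusted p = 0.399), anti-apoptotic genes (0.202), antioxidant response genes (0.0581) and proliferation genes (0.067) were not called. The p53 target Bbc3 stood at 0.31, the quinone reductase gene Nqo1 at -0.37 and the proliferation marker Mki67 at -0.29. By edgeR no member of these 4 lists was called over all genes tested, and adjusted over the list alone 1 anti-apoptotic gene was. Antioxidant genes were called lower without WT 1 (camera adjusted p = 0.0407), WT 2 (0.0335), E-cad-KO 1 (0.0388), E-cad-KO 2 (0.018) or E-cad-KO 3 (0.0387). They also were with upper-quartile scaling (0.0497), the 1 CPM filter (0.0438) and the macrophage covariate (0.0409). Proliferation genes were called lower without WT 1 (0.0248), WT 4 (0.0152), E-cad-KO 4 (0.0247) or E-cad-KO 5 (0.00223). They also were without both WT 1 and WT 4 (0.000476), with length and GC offsets (0.0316) and with upper-quartile scaling (0.0497).

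Also not called were basal (camera adjusted p = 0.949) and luminal epithelial genes (0.633), Wnt and beta-catenin targets (0.998) and the Notch pathway (0.759). The same held for collagens and matrix (0.149), matrix proteases (0.149), cholesterol synthesis (0.651), glycolysis and hypoxia (0.614) and the unfolded protein and integrated stress response (0.733). Adjusted over the list alone, 3 luminal genes were higher and 1 lower, 2 Wnt targets lower, 2 Notch genes higher, 1 collagen and matrix gene higher and 2 matrix protease genes higher. Camera's direction was upward against a negative median and mean for Wnt targets, a negative mean for the Notch pathway and a negative median for collagens. Collagens were called without WT 3 (camera adjusted p = 0.00752) or WT 4 (0.0449), matrix proteases (0.0216) and glycolysis (0.00193) without WT 4, and cholesterol synthesis (0.0145) without WT 1. Without both WT 1 and WT 4, matrix proteases (0.0324) and glycolysis (0.0482) were called.

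Over the lists with 0 members called by edgeR, the members at an unadjusted p under 0.05 were 0 for desmosomes, other cadherins, basal genes, macrophage markers and lymphocyte markers. They were 12 higher and 1 lower for TGF-beta response, 6 each for tight junctions, epithelial identity, p53 targets and ERK genes, and 2 for adherens junction partners, these all higher. DESeq2 called 10 TGF-beta response, 2 tight junction, 3 epithelial identity, 2 p53 and 3 ERK genes, all higher, and limma-voom called 1, 2, 1, 1 and 2 genes of these lists. In simulated data 20.5% of DESeq2's calls were false. For adherens junction partners both called 0. Of the EMT transcription factors 2 higher and 1 lower were at an unadjusted p under 0.05, and DESeq2 called 2 and limma-voom 0. At that p were 3 higher and 2 lower luminal genes, 3 higher and 2 lower Notch genes, and 2 higher and 3 lower Wnt targets. So were 5 proliferation and 4 antioxidant genes, all lower, and 3 pro-apoptotic and 2 anti-apoptotic genes, all higher. Of luminal genes DESeq2 called 3 higher and 1 lower, and limma-voom 2 higher and 1 lower. DESeq2 called 2 Notch genes higher and 1 Wnt target, 1 proliferation gene and 1 antioxidant gene lower, of which limma-voom called 0. Each tool called 1 pro-apoptotic and 1 anti-apoptotic gene higher. The other lists with 0 edgeR calls had at most 1 member higher and 2 lower at that p, and at most 1 call by either tool.

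Markers of other cell types varied widely within the groups. The macrophage score ran from -1.92 in WT 1 to 2.48 in WT 4 and from -0.99 to 1.32 in E-cad-KO, and Lyz2 from 10.8 to 307 CPM within WT. Macrophage markers had a median log2 fold change of -0.74 and were not called (camera adjusted p = 0.789), nor were fibroblast (0.823), endothelial (0.0955) or pericyte and muscle markers (0.823, with a negative median against an upward direction). Fibroblast and endothelial markers were called lower without WT 1 (camera adjusted p = 0.00799 and 0.00106), and endothelial markers also without WT 2 (0.0335), without both WT 1 and WT 4 (0.0263), with length and GC offsets (0.0374) and with the filter of at least 1 count (0.0267). Lymphocyte and adipocyte markers had 2 and 4 tested members and were not tested. Their median log2 fold changes were -0.31 and -1.35, and 2 adipocyte genes were past the threshold adjusted over the list alone. The first principal component held 63.3% of the variance with WT 1 and WT 4 at its ends, and the second held 10.6%, on which each WT library lay above each E-cad-KO library. With the macrophage score as a covariate 1188 genes were called, among them all 244, and 79 were called without both WT 1 and WT 4.

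**Figure D4:**
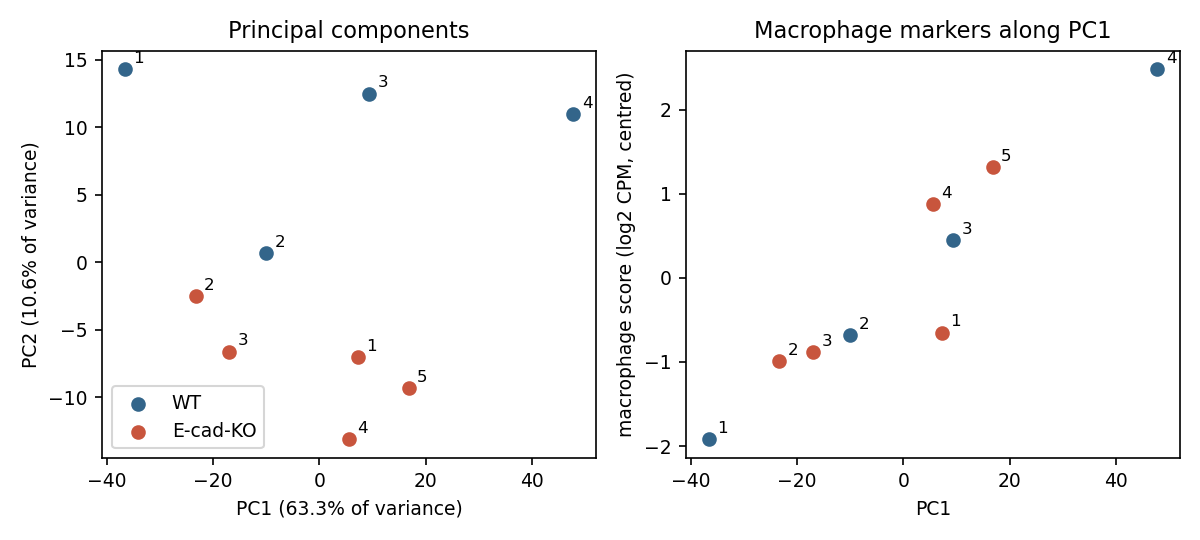
Left, the 9 libraries on the first and second principal components (63.3% and 10.6% of the variance); right, their macrophage score (mean centred log2 CPM) against the first component, with replicate numbers beside the points. WT 1 and WT 4 lie at the ends of the first component, with macrophage scores of -1.92 and 2.48.

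For 12 of the 15 called lists, at least 5 of 100 splits of the 9 libraries into groups of 4 and 5 gave a p-value as small as the real one. YAP and TAZ targets, milk genes and actomyosin were the exceptions, in counts not adjusted over the lists. By an exact two-sided permutation test of the scores, these lists and TGF-beta response each had p = 0.00794, the smallest possible here. Adjusted over all 38 lists, that permutation p was 0.0754 for each, so no list passed 0.05. Because each of these lists already stood at the smallest possible p, this adjustment does not decide for or against them. Genes called lower had a median transcript length of 2101 nt, genes called higher 4020 nt and genes not called 3034 nt, and with offsets for length and GC content 157 genes were called, 129 of them among the 244.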

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

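These results stand out because 1 library lies far from the others of its group, measured as its gap to the nearest library over the range of the group. Of 300 groups tested, 17 stood out, where chance gives about 1 in 20, or 15. The tests of macrophage content and of genotype were chosen after the result was seen.

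In WT 4, Cd68 stood at 22.0 CPM against 3.31 to 5.99 in the other WT libraries (gap 0.857 of the range). WT 4 was low for Spint2 (120 against 170 to 174 CPM, 0.917) and for the scores of basal epithelial genes (0.973), TGF-beta response (0.836) and immediate early and heat shock genes (0.866). It also had the highest macrophage score of the 9 libraries, and a candidate explanation of the score's spread is that macrophages were carried along in different amounts. A macrophage gene correlated with the mean of the others at a median of 0.97 over the libraries, and between WT 1 and WT 4 Lyz2 went from 10.8 to 307, C1qa from 0.25 to 8.14 and Tyrobp from 0.07 to 13.8 CPM. Genotype as the whole cause is argued against by the range of 4.40 within WT, with group means of 0.08 and -0.06; whether macrophages bear on the other values of WT 4 was not tested.

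Cdh1 itself was high in E-cad-KO 2, at 118 CPM against 79.0 to 87.3 in the other E-cad-KO libraries (0.790), and below all WT libraries. Foxj1 was high in WT 2 (8.79 CPM, 0.834) and Mtus1 low in E-cad-KO 4 (26.5 CPM, 0.742). Also in E-cad-KO 2, Mgst1 was high at 635 CPM (0.845) and the score of Wnt and beta-catenin targets low at -0.30 (0.734). E-cad-KO 5 was low for Mcm7 (86.7 CPM, 0.844, overlapping Ap4m1 and Cops6 on the other strand), Hspb1 (87.7 CPM, 0.739) and mt-Nd1 (0.740) and high for Areg (37.9 CPM, 0.763) and Itgb1 (0.851). Krt8 was high in WT 2 (0.857), and Nox4 low in WT 1 at 16.4 CPM (0.830).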

How the results depend on the processing

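Chosen after seeing the data were the macrophage covariate, the removal of WT 1 and WT 4, the length and GC offsets and the counts over splits. In each alternative, those of the 244 called genes that were tested kept their direction. Against 244 calls (157 higher, 87 lower), DESeq2 made 1206 (714 and 492), though 20.5% and 20.9% of its calls were false in the simulations, over the 20% limit set beforehand. Counts of 511 (298 and 213) came from limma-voom, of 1188 (704 and 484) from the macrophage covariate. Upper-quartile scaling gave 151 lower calls and the 1 CPM filter 135. Length and GC offsets gave 157 (99 higher), and leaving out WT 1 and WT 4 gave 79 (48 and 31). A minimum fold of 1.5 in glmTreat left 0 (0 higher, 0 lower), with 234 at an unadjusted p under 0.05. Leaving out 1 library gave 9 to 334 calls, 8 to 193 higher and 1 to 141 lower: 122 without WT 1, 105 without WT 2, 9 without WT 3, 334 without WT 4, and 29, 54, 28, 26 and 47 without E-cad-KO 1 to 5. Smaller groups are part of this by construction; why WT 3 weighs most was not tested. The Cdh1 log2 fold change stayed at -0.89 to -1.16 in these runs and its call was lost in 5 of 9 (edgeR adjusted p 0.0644 to 0.0904), as without WT 1 and WT 4 (-0.94); over the 19 alternatives that recorded it (not glmTreat or robust=FALSE) its adjusted p ran from 5.5e-08 to 0.171. The replicate numbers were not taken to pair the samples, since the labels do not say so and same-numbered libraries deviated from their group means with correlations of -0.32, 0.23, -0.03 and 0.28, not all over 0.1. Whether preparations were shared is open. With the number as a replicate block edgeR called 0 genes (0 higher, 0 lower), 2418 having an unadjusted p under 0.05, and the Cdh1 log2 fold change was -0.99 (adjusted p = 0.171). In that fit the camera call of mitochondrial mRNAs was lost (adjusted p = 0.065) and proliferation genes were called lower (0.0092). Depth limits genes below 1 CPM most, which was 44.9 counts in the smallest library. Of 15 called lists, 1 remained with estimated correlations and 5 in fry's directional test.

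Of 100 splits of the 9 libraries into 4 and 5, 1 gave 244 genes or more, the real one, and the highest other gave 142. That split set WT 1, WT 2, E-cad-KO 2 and E-cad-KO 3 against the rest, along the first principal component. The splits argue against chance for the number of called genes, but 100 splits of 9 libraries cannot exclude it. By genes at an unadjusted p under 0.05 the real split had 2893, and 3 splits, the real one included, had as many, the highest other at 3493. For the number of lists the splits do not argue against chance, as 27 gave 15 or more and the highest other gave 20. A p as small as the real one came in 1 split for YAP and TAZ targets, 3 for milk genes and 4 for actomyosin. It came in 5 for TGF-beta response and for immediate early genes, 9 for TGF-beta ligands and for integrins, 12 for interferon, 15 for tight junctions and for NF-kB genes, 16 for ERK, 20 for p53, 21 for mitochondrial mRNAs and 48 for adherens junction partners and for epithelial identity.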

Other observations

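The tests in this part were chosen after their results or related values were seen, except the matched sets for respiratory chain genes and the cilium list, which were fixed after the genes that prompted them were seen and before the tests were run.

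Subunits of the respiratory chain encoded in the nucleus were lower in E-cad-KO for 75 of 79 genes, with a median log2 fold change of -0.19; 9 were called, all lower, among them Ndufb11 (-0.28, overlapping Rbm10 on the other strand), Ndufa5 (-0.27), Atp5k (-0.30) and Uqcr11 (-0.25). The set was chosen after called members were seen. Their median transcript length was 1046 nt, and short transcripts as a whole were lower in the E-cad-KO libraries: the slope of centred log2 expression per doubling of length was -0.0219 ± 0.0198 in WT (SD, n = 4) and 0.0175 ± 0.0159 in E-cad-KO (SD, n = 5; exact permutation p = 0.0238, two-sided). Sets of other genes matched on length and expression had a median of -0.07, and 0.01% of 10000 sets, the smallest share they can give, were as low. The same share came from a match on CCDS transcript length, added after the first result was seen. This argues against a general deficit of short transcripts as the whole explanation, although respiratory chain genes vary together and random sets do not. With length and GC offsets the median was -0.11 (exact permutation p of the score = 0.0238, two-sided, n = 4 and n = 5), so part of the difference may follow length. As the length trend follows the groups, its source is confounded with genotype.

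Transcript length or GC content as the whole cause of the 244 calls is argued against by the offsets, under which the median size of the called genes' log2 fold change was 94.1% of that without them (0.46 before and 0.43 after, with a median SE of 0.08 both times). It was 93% for genes called higher and 90.2% for genes called lower. With the offsets 157 genes were called, 129 of them among the 244, so the other calls were lost. Because the 244 genes were selected in the fit without offsets, the kept size does not show which single calls hold apart from the trend. The called genes' changes were slightly smaller against a like error.

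A candidate explanation for the higher interferon response is macrophage content, but with the macrophage score as a covariate the median log2 fold change of the list was 0.58 against 0.59 (camera adjusted p = 1.07e-05, with a range over the alternatives of 8.49e-12 to 0.472). The macrophage score itself hardly differed between the groups, with means of 0.08 (SD 1.87) in WT and -0.06 (SD 1.08) in E-cad-KO. By this score macrophage RNA was not higher on average in E-cad-KO. Because the covariate was so little related to group, the unchanged median cannot decide whether macrophage content bears on the list. The sampling of libraries is open too, since 12 of 100 splits gave a p as small.

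Foxj1, Efhb (log2 fold change 1.53) and Cys1 (1.33) were called higher in E-cad-KO and Cfap43 (0.65, edgeR adjusted p = 0.0511, overlapping Itprip on its own strand) was not. Efhb (mean 0.27 CPM in WT and 0.79 CPM in E-cad-KO) and Cys1 (0.44 and 1.11 CPM) had low counts. These values raised the hypothesis of a motile cilium programme, of which Foxj1 is the master regulator. In a list of 40 other cilium genes, 20 were tested, 13 were higher, edgeR called 0 and 1 had an unadjusted p under 0.05. The median was 0.19 (camera p = 0.19, exact permutation p of the score = 0.421, two-sided, n = 4 and n = 5). The list gave no answer either way, many members lying near or below 1 CPM.

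Some gene groups varied between libraries of both genotypes, in a family of 3 correlations over 9 libraries with exact two-sided permutation tests. Glycolysis and hypoxia scores ran against macrophage scores (Pearson r = -0.82, p = 0.00681, adjusted 0.00681; Spearman rho = -0.88, p = 0.00308, adjusted 0.00462; r = -0.63 without WT 4 and E-cad-KO 5). Krt6a, a keratin of squamous cells whose exons overlap 2 unnamed genes on the other strand, went from 1839 CPM in WT 1 to 92.7 CPM in WT 4. EMT transcription factor scores, without the member shared with the fibroblast list, followed fibroblast scores (r = 0.94, p = 0.000325, adjusted 0.000975; rho = 0.93, p = 0.00075, adjusted 0.00225; r = 0.83 without WT 1 and WT 4), as did log2 CPM of Vim (r = 0.85, p = 0.00519, adjusted 0.00681; rho = 0.75, p = 0.0255, adjusted 0.0255; r = 0.59 without the same libraries). Fibroblast RNA may therefore account for part of the spread of these genes; epithelial cells that express both cannot be excluded by bulk counts.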
